A study of Bos taurus with 160 samples.

How the data were processed

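Transcript levels were measured with Affymetrix bovine arrays on RNA from liver, placenta, caruncular endometrium and intercaruncular endometrium of pregnant Holstein cows, 1 array per sample and 160 arrays in all. The authors provided 1 table of normalized probe set values, which were read as log2 signals because they run from about 2 to 17. The scale and the methods of background correction, normalization and summarization are not stated with the deposited values. limma is the only tool the authors name, without a version or a role. Within a tissue, the lowest value was shared exactly by the arrays: 2.044 in liver, 2.023 in intercaruncular endometrium, 2.017 in caruncular endometrium and 2.006 in placenta, apart from 3 arrays labelled caruncular that carried the intercaruncular value. The tissues had therefore been normalized in separate sets, and each tissue was fitted on its own.

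The table held 24128 probe sets, of which 112 array controls were left out and 24016 kept. The annotation gave 1 gene symbol for 13292 of them, several for 86 and none for 10638. A reference gene table held the symbols of 13263 of the single-symbol probe sets, which were 9155 distinct genes, and 0 symbols had to be updated. Where a gene had several probe sets, the probe set with the highest mean in the tissue stood for it. For the largest rises and falls, it was the called probe set with the highest mean. A probe set was tested in a tissue when its signal exceeded the tissue's lowest value by more than 0.1 log2 units on at least 1 array. This margin was set from the lowest value after the values had been seen and before any test was run. It left 18026 probe sets in liver, 18771 in intercaruncular endometrium, 19002 in caruncular endometrium and 18740 in placenta. Between 23.2% and 28.4% of the probe sets of an array were at the lowest value, where no further fall can be seen. For arrays, only their number limits the precision that can be stated.

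In each tissue, limma 3.58.1 in R 4.3.3 fitted 1 mean for each of the 6 combinations of lactation and day, plus a term for season group. The labels define season group 1 as March to July and season group 2 as September to December. The lactation effect was the mean difference, lactating minus non-lactating, over the 3 days, and each day effect was the mean difference over both lactation states. The interaction asked whether the lactation effect changed with day. Differences of the lactation effect between liver and each other tissue, the difference of the day effect between the endometrial regions, and the level in caruncular minus intercaruncular endometrium were fitted on the arrays of both tissues together. Arrays of different tissues from the same cow were treated as independent there. Moderated limma tests were adjusted by the Benjamini-Hochberg method, and a probe set was called at an adjusted p under 0.05. The design balances lactation over the days, while non-lactating day 42 had 1 cow of season group 1.

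A set of 36 gene lists was written before the data were examined, and 35 had the required 5 measured genes in at least 1 tissue. They cover the GH-IGF axis, gluconeogenesis, fatty acid oxidation, lipogenesis, cholesterol synthesis, lipoproteins, urea and amino acid metabolism, and steroid and xenobiotic metabolism. Others are the acute phase, the unfolded protein response, oxidative phosphorylation, glycolysis and hypoxia, and cell cycle. The list called stress response here holds early response genes of stress and of tissue dissociation. They also cover interferon-stimulated genes, MHC, steroid receptors, prostaglandin metabolism, uterine gland products, nutrient transporters, extracellular matrix, angiogenesis, imprinted genes, trophoblast secretory products, trophoblast transcription factors and placental steroid synthesis. Marker lists for other cells were hepatocytes, leukocytes, plasma cells, endothelium, epithelium, stroma, smooth muscle, yolk sac and erythroid cells. Each list was tested against the other measured genes with limma's competitive test at a preset correlation of 0.01, and again with a correlation estimated from the arrays, and adjusted over the lists of a comparison. The members of a list were also adjusted over the list alone.

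The genes to be named were fixed by a rule. It took the 10 largest rises and 10 largest falls among called probe sets with 1 symbol, and up to 4 members with the smallest p of any list that passed its test or had at least 3 called members. It took the 3 genes with the smallest p where nothing passed and for the interaction, season and difference comparisons. GHR, IGF1, PGR, ESR1, OXTR, ISG15, SERPINA14, PAG1, CSH2, CYP11A1 and CYP19A1 were always included. The probe set for ESR1 stayed at the lowest value and was not tested, and PAG1 was not in the annotation.

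The comparisons, gene lists, naming rule and most alternatives were set before the data were examined. These alternatives dropped the season term, left out dim probe sets, added quantile normalization, used trended and robust variances, used array weights, dropped the interaction, added a fold of at least 1.5, used each season group alone, took the number in the sample titles as a block, or left out single arrays of the smallest group. Leaving out arrays that stood apart or belonged to an unusually similar pair, singly or as sets of 3, and a block for the cow over both tissues were chosen after seeing the data. For each count of called probe sets, 100 regroupings of the arrays, the real one included, were drawn. The procedure was tested on simulated data. With Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, per-array checks and figures were made. Raw image files were not analysed here.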

Results

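The data were transcript profiles of liver, placenta and both regions of the endometrium from Holstein cows in early pregnancy, some lactating and some not. Caruncles are the raised areas of the uterine lining to which the ruminant placenta attaches, and the intercaruncular endometrium between them carries the uterine glands. Liver gave 41 arrays (22 lactating, 19 non-lactating), caruncular endometrium 41 (22 and 19), intercaruncular endometrium 38 (21 and 17) and placenta 40 (22 and 18). Over days 28, 35 and 42 of pregnancy these were 13, 14 and 14 arrays in liver and in caruncular endometrium, 13, 11 and 14 in intercaruncular endometrium, and 12, 14 and 14 in placenta. The smallest group was non-lactating intercaruncular endometrium on day 35, with 4 arrays. The median log2 signal per array ran from 5.60 to 5.74 in liver, 6.45 to 6.58 in intercaruncular endometrium, 6.23 to 6.65 in caruncular endometrium and 6.34 to 6.58 in placenta. An array's correlation with the others of its tissue had a median of at least 0.991 in each tissue, with lowest values of 0.95 in placenta and 0.955 in caruncular endometrium. Of the arrays labelled caruncular, 3 from day 35 (lactating replicate 8, non-lactating replicates 4 and 5) carried the lowest value of the intercaruncular arrays, 2.023.

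**Figure D1:**
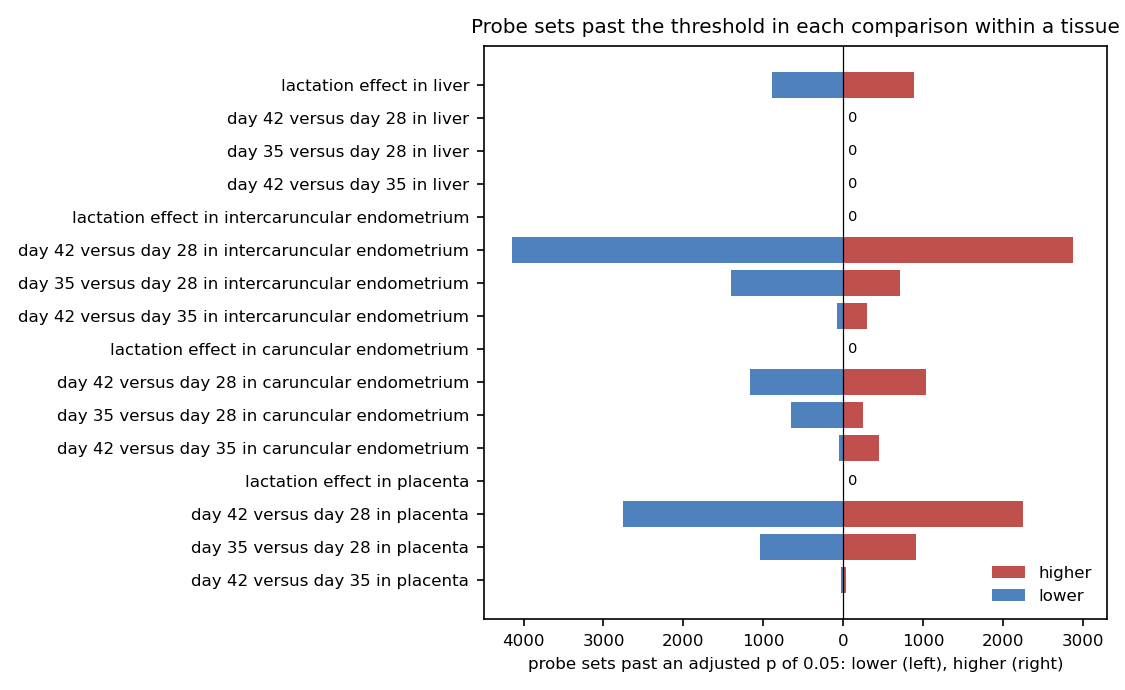
Number of probe sets called at an adjusted p under 0.05 (x axis: number of probe sets, bars to the left for lower and to the right for higher; y axis: comparison within each tissue). Lactation gave 1776 called probe sets in liver and 0 in the other 3 tissues, while day 42 against day 28 gave 0 in liver, 2195 in caruncular endometrium, 7020 in intercaruncular endometrium and 5003 in placenta.

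The first comparison asked how lactation alters the liver of a pregnant cow. In liver, SOCS2, an inhibitor of growth hormone signalling, rose by 2.31 ± 0.35 log2 units in lactating cows (SE; n = 22 lactating and 19 non-lactating; adjusted p = 1.9e-05) and was above the non-lactating median in 22 of 22 lactating arrays. The binding proteins of insulin-like growth factors IGFBP1 and IGFBP2 rose by 1.78 ± 0.33 and 1.05 ± 0.16, each above the non-lactating median in 22 of 22 arrays (adjusted p = 0.00031 and 1.9e-05). GHR, the growth hormone receptor, fell by 0.48 ± 0.14 (adjusted p = 0.026) and was below the non-lactating median in 17 of 22 arrays, while 0 of its 10 other probe sets passed. IGF1 differed by 0.10 ± 0.20 (adjusted p = 0.8). Of the 15 measured genes of the GH-IGF axis, 3 rose and 1 fell (4 and 1 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.19).

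In the lactating liver most genes of cholesterol synthesis rose, and some of lipogenesis. Of 17 cholesterol synthesis genes, 15 rose and 0 fell, with the same counts adjusted over the list alone, and the median change was 0.43. FDPS, which makes farnesyl pyrophosphate, rose by 0.80 ± 0.11, DHCR7 by 0.85 ± 0.12, NSDHL by 0.36 ± 0.05 and MSMO1 by 0.22 ± 0.03, each above the non-lactating median in 22 of 22 lactating arrays. The list passed at an adjusted p of 6.6e-17 with the preset correlation, and gave adjusted p = 0.1 with an estimated correlation. Of 21 lipogenesis genes, 6 rose (8 adjusted over the list alone) and 0 fell, with adjusted p = 0.0012, or adjusted p = 0.1 with an estimated correlation. SCD, the stearoyl-CoA desaturase, rose by 1.23 ± 0.18, ACSS2 by 1.16 ± 0.16, FASN, the fatty acid synthase, by 1.11 ± 0.17 and ACLY by 0.77 ± 0.12. Lipoprotein genes moved both ways, 5 of 19 rising and 5 falling (6 and 6 adjusted over the list alone; adjusted p = 0.97 for the list). Among them APOA4 rose by 1.43 ± 0.24 and APOA1 by 0.56 ± 0.07.

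In the gluconeogenesis and glucose list, 7 of 19 genes rose and 3 fell (9 and 3 adjusted over the list alone), and the list gave adjusted p = 0.057. PC, pyruvate carboxylase, rose by 0.93 ± 0.13 (adjusted p = 5.1e-06) and PCK1, which makes phosphoenolpyruvate, by 0.37 ± 0.06. The aminotransferase GOT1 fell by 0.65 ± 0.10 and was below the non-lactating median in 21 of 22 arrays. Of 22 genes of glycolysis and hypoxia, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with adjusted p = 0.011, or adjusted p = 0.1 with an estimated correlation. P4HA1 rose by 0.77 ± 0.14. Fatty acid oxidation genes split, 5 of 22 rising and 3 falling (6 and 3 adjusted over the list alone; adjusted p = 0.71, median −0.02 against a test direction of up). ACSL1, which activates fatty acids, rose by 0.42 ± 0.07 and HADH fell by 0.14 ± 0.03. Of 20 genes of urea and amino acid metabolism, 6 fell and 1 rose (7 and 5 adjusted over the list alone; adjusted p = 0.11). OTC, the urea cycle enzyme ornithine carbamoyltransferase, fell by 0.42 ± 0.05 (adjusted p = 1.4e-07), and the glutaminase GLS2 by 0.60 ± 0.08. Of 44 oxidative phosphorylation genes, 5 fell and 1 rose, also when adjusted over the list alone, with a median of −0.05 and adjusted p = 0.0046, or adjusted p = 0.69 with an estimated correlation.

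The largest rises after SOCS2 were AK4 (2.23 ± 0.42), MFSD2A (2.19 ± 0.32), GPNMB (2.09 ± 0.32) and CYP11A1 (2.01 ± 0.31), the cholesterol side-chain cleavage enzyme. CYP11A1 belongs to the placental steroid synthesis list, of which 2 of 11 genes rose (3 adjusted over the list alone; adjusted p = 0.049, or adjusted p = 0.14 with an estimated correlation). GPX3, LRRC8E and CDHR5 rose by 1.99 ± 0.43, 1.91 ± 0.21 and 1.82 ± 0.52. The largest falls were SFRP2 (−2.03 ± 0.58), SLA2 (−1.84 ± 0.21), ZP2 (−1.58 ± 0.40), GSDMB (−1.57 ± 0.13) and CD200 (−1.48 ± 0.27). GSDMB was below the non-lactating median in 22 of 22 lactating arrays (adjusted p = 7.7e-10). Of the marker lists for other cell types, 0 of 31 leukocyte, 0 of 13 endothelial, 0 of 15 stromal fibroblast, 0 of 6 plasma cell and 0 of 9 erythroid genes passed (2 erythroid genes fell adjusted over the list alone). Of 13 smooth muscle markers 2 rose, of 14 epithelial markers 1 rose and 1 fell, and of 16 yolk sac markers 2 rose and 1 fell. SELP, an adhesion molecule of endothelium and platelets outside these lists, fell by 1.21 ± 0.18. Of 17 hepatocyte markers 4 fell and 1 rose (4 and 2 adjusted over the list alone; adjusted p = 0.2, mean 0.01 against a median of −0.03). Of 19 steroid and xenobiotic metabolism genes, 3 fell and 1 rose (adjusted p = 0.28), and of 21 acute phase genes 2 fell and 1 rose (adjusted p = 0.14). Of 25 stress response genes 4 rose, ATF3 by 0.94 among them (adjusted p = 0.28). Of 19 imprinted genes, NAP1L5 rose by 1.27 ± 0.23 and MEST fell by 0.51 ± 0.13 (2 and 1 called, 4 and 1 adjusted over the list alone; adjusted p = 0.28).

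In all, limma called 1776 of 18026 probe sets in liver, 883 higher and 893 lower, for 1003 genes, with a median absolute change of 0.28. Season group 1 alone (15 arrays) held 1 non-lactating day 42 array, so only the sizes of its effects are given. In season group 2 alone (26 arrays) 910 probe sets were called. In these groups SOCS2 was higher by 1.81 and 2.63, GHR lower at −0.53 and −0.50, SCD higher by 1.11 and 1.36, and GSDMB lower at −1.72 and −1.53. A fold of at least 1.5 was reached by 271 probe sets, and a block for the number in the sample titles left 618. MYC (1.13) lost its call at 1.10 without lactating day 35 replicate 7. That array and lactating day 28 replicate 5 may come from 1 cow, as described below. The lactating arrays may therefore count 1 cow 2 times.

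**Figure D2:**
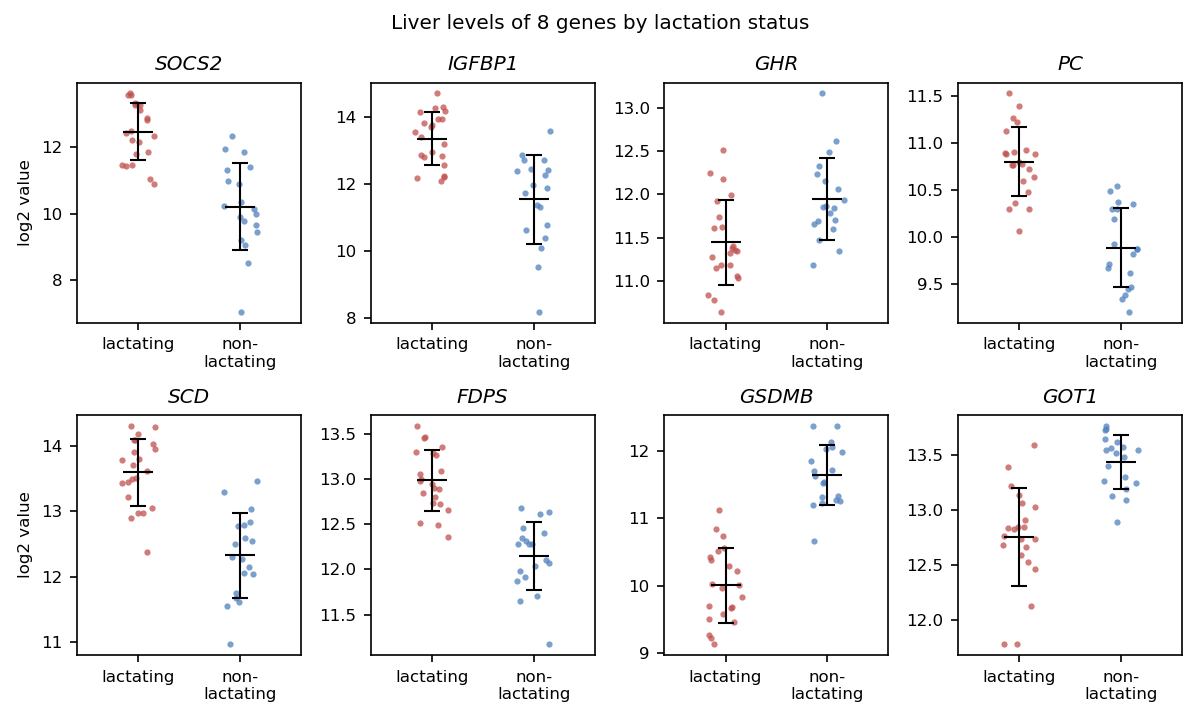
Log2 signal in liver of 8 genes named in the text (y axis) in 22 lactating and 19 non-lactating arrays (x axis; dots are arrays, bars mean ± SD). SOCS2, IGFBP1, PC, SCD and FDPS lie higher in lactating cows and GHR, GOT1 and GSDMB lower, with differences from 2.31 (SOCS2) to −1.57 (GSDMB).

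The same question was put to the tissues of the pregnancy itself, where limma called 0 probe sets for lactation. At an unadjusted p under 0.05 there were 556 in intercaruncular endometrium, 507 in caruncular endometrium and 1130 in placenta, where 939, 950 and 937 would be expected by chance. In intercaruncular endometrium the genes of smallest p were SGO2 (0.51 ± 0.12), PNP (−0.23 ± 0.06) and ZNF197 (0.19 ± 0.05), and in caruncular endometrium MAFF (0.41 ± 0.11), GCNT1 (0.32 ± 0.09) and PPM1K (−0.84 ± 0.23), each with adjusted p = 1. In placenta they were RIDA (−0.20 ± 0.04), UBD (−0.46 ± 0.11) and MCOLN2 (−0.72 ± 0.17), each with adjusted p = 0.57. The placental lactogen CSH2 differed by −0.18 ± 0.25 in placenta. The interferon-stimulated gene ISG15 differed by −0.01 ± 0.48 in intercaruncular and −0.24 ± 0.44 in caruncular endometrium, and the uterine serpin SERPINA14 by 0.04 in both regions. PGR, the progesterone receptor, was at the lowest value in 22 of 22 lactating and 18 of 19 non-lactating caruncular arrays, so that only a higher level in 1 of the groups could have been seen there. In season group 2 alone 2 probe sets were called in placenta. Season group 1 alone held 1 non-lactating day 42 array in each tissue, so no count is given for it.

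Gene lists leaned with lactation in these tissues without a called member, and none of these tests held with an estimated correlation. Cholesterol synthesis was lower in intercaruncular endometrium (median −0.11; adjusted p = 9.3e-06, or adjusted p = 0.66 with an estimated correlation; 0 of 17 genes called, INSIG1 −0.28 and CYP51A1 −0.28). In caruncular endometrium 9 lists passed at the preset correlation, the first being hepatocyte markers (median 0.49; adjusted p = 2.3e-07, or adjusted p = 0.51 with an estimated correlation). Among them APOA2 was at the lowest value in 17 of 22 lactating and 16 of 19 non-lactating arrays. The list mean was 9.33 in lactating day 42 replicate 4 and 8.06 and 8.0 in lactating day 28 replicates 3 and 2, against a median of 4.63 over the 26 arrays of season group 2, to which these 3 belong. In placenta 16 lists passed, led by hepatocyte markers (median −0.93; adjusted p = 3.9e-09, or adjusted p = 0.098 with an estimated correlation; 9 of its genes lower adjusted over the list alone). Yolk sac markers passed as well (median −0.58; adjusted p = 6.9e-07, or adjusted p = 0.11 with an estimated correlation). APOB differed by −2.24 ± 0.80 there (adjusted p = 0.78). Without 3 day 28 placenta arrays that stood apart (non-lactating replicate 2, lactating replicates 5 and 6), 12 lists passed. The hepatocyte median was then −0.62 (adjusted p = 5.9e-05, or adjusted p = 0.46 with an estimated correlation), the yolk sac median −0.36 (adjusted p = 0.00035, or adjusted p = 0.46 with an estimated correlation) and APOB −1.29. The yolk sac mean had been 11.78 in the non-lactating and 7.52 and 7.74 in the lactating arrays of the 3, so these arrays carried part of the difference. The trophoblast secretory list turned from down (adjusted p = 0.00067) to up (adjusted p = 0.2).

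The difference between tissues was tested directly. The lactation effect in liver differed from that in intercaruncular endometrium for 542 probe sets (304 more positive and 238 more negative in liver), from that in caruncular endometrium for 430 (220 and 210) and from that in placenta for 601 (288 and 313). The nuclear pore gene NUP62 differed by 1.16 ± 0.11, 1.13 ± 0.10 and 1.15 ± 0.11 in these comparisons (limma, adjusted p = 7.4e-12, 3.4e-12 and 1e-12). The 1 other probe set of NUP62 was not called in any of them. GSDMB differed by −1.57 ± 0.16, −1.65 ± 0.17 and −1.62 ± 0.15. In liver, all 22 lactating arrays were beyond the non-lactating median for both genes. NFYB, a subunit of a CCAAT-binding factor, differed by −0.83 ± 0.08 from intercaruncular and −0.80 ± 0.08 from caruncular endometrium. Of 17 cholesterol synthesis genes, 13, 10 and 12 were more positive in liver (14, 15 and 16 adjusted over the list alone) and 0 more negative. The list passed with an estimated correlation as well (adjusted p = 0.0039, 0.0071 and 0.0057). Of 21 lipogenesis genes, 6, 5 and 6 were more positive (6, 7 and 7 adjusted over the list alone) and 0 more negative, again with an estimated correlation (adjusted p = 0.013, 0.015 and 0.013).

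The second question was how the endometrium changes between days 28 and 42, as the placenta attaches. In intercaruncular endometrium from day 28 to day 42, the antimicrobial peptide DEFB4A rose by 4.39 ± 0.51 log2 units (SE; n = 14 on day 42 and 13 on day 28; adjusted p = 4.6e-07) and the annexin ANXA10 by 4.32 ± 0.55. PRLR, the prolactin receptor, rose by 3.25 ± 0.34 (above the day 28 median in 14 of 14 arrays) and the extracellular superoxide dismutase SOD3 by 2.77 ± 0.24. In caruncular endometrium ANXA10 rose by 3.78 ± 0.41 (14 of 14 arrays; adjusted p = 6e-07), PRLR by 3.05 ± 0.34, DEFB4A by 3.34 ± 0.62 and the transferrin receptor TFRC by 4.40 ± 0.63. MPTX1, BPIFB1, PIP and CRIPTO fell in both regions, by 3.12 ± 0.57, 2.96 ± 0.47, 2.57 ± 0.37 and 2.35 ± 0.35 in intercaruncular and by 2.54 ± 0.64, 2.23 ± 0.47, 2.15 ± 0.46 and 2.11 ± 0.50 in caruncular endometrium. OXTR, the oxytocin receptor, rose by 0.68 ± 0.15 in intercaruncular (14 of 14 arrays; adjusted p = 0.00053) and 1.10 ± 0.27 in caruncular endometrium (13 of 14 arrays; adjusted p = 0.0071). SERPINA14 rose by 0.19 ± 0.06 in each. PGR was at the lowest value in 13 of 14 day 42 and 10 of 13 day 28 intercaruncular arrays, and in 14 of 14 and 12 of 13 caruncular arrays, so that a fall could hardly have been seen.

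Interferon-stimulated genes were lower after day 28. From day 28 to day 35, 24 of 39 fell and 0 rose in intercaruncular endometrium (27 and 0 adjusted over the list alone; median −0.84; adjusted p = 1.8e-10, or adjusted p = 0.41 with an estimated correlation). ISG15 fell by 2.98 ± 0.60 and the antiviral gene RSAD2 by 2.46 ± 0.51. In caruncular endometrium 8 of 39 fell (28 adjusted over the list alone; median −0.72; adjusted p = 3.9e-07, or adjusted p = 0.48 with an estimated correlation). IFI6 fell there by 1.30 ± 0.30. Without the 3 arrays labelled caruncular that carry the intercaruncular lowest value, 0 of the 39 were called (7 lower adjusted over the list alone; median −0.60; adjusted p = 3.5e-08, or adjusted p = 0.5 with an estimated correlation). From day 28 to day 42, 21 fell and 1 rose in intercaruncular endometrium (22 and 2 adjusted over the list alone; adjusted p = 0.002, or adjusted p = 0.7 with an estimated correlation). There ISG15 fell by 2.48 ± 0.56 and was below the day 28 median in 13 of 14 arrays. IFI30, a lysosomal reductase, rose by 0.89 ± 0.19. In caruncular endometrium 4 fell and 0 rose over that interval (20 and 2 adjusted over the list alone; adjusted p = 6.7e-05, or adjusted p = 0.7 with an estimated correlation). IFI6 fell by 1.18 ± 0.30, and ISG15 differed by −1.58 ± 0.54 (adjusted p = 0.051). IFI44L and RSAD2 lost their calls without non-lactating day 28 replicate 5 or without lactating day 42 replicate 4. The mean of the list was 9.25 on day 28 (SD 0.87, n = 13), 8.21 on day 35 (SD 0.28, n = 11) and 8.50 on day 42 (SD 0.59, n = 14) in intercaruncular endometrium. It was 9.37, 8.61 and 8.79 in caruncular endometrium, where the day 35 mean includes those 3 arrays.

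Cell cycle genes were higher on day 42 than on day 35. In caruncular endometrium 22 of 38 rose and 0 fell (31 and 0 adjusted over the list alone; median 0.43; adjusted p = 5.9e-23, or adjusted p = 0.26 with an estimated correlation). NCAPG, a condensin subunit, rose by 1.65 ± 0.30 and BIRC5 by 1.95 ± 0.35. In this comparison trophoblast secretory genes rose as well, 8 of 31 (12 adjusted over the list alone; adjusted p = 0.0001, or adjusted p = 0.87 with an estimated correlation). Without the 3 arrays labelled caruncular that carry the intercaruncular lowest value, limma called 0 probe sets in this comparison, so these calls ended, those of NCAPG and BIRC5 among them. The cell cycle list then had 27 genes higher adjusted over the list alone (adjusted p = 3.4e-29, or adjusted p = 0.13 with an estimated correlation). In intercaruncular endometrium 2 of 37 rose (20 adjusted over the list alone; adjusted p = 3.5e-08, or adjusted p = 0.82 with an estimated correlation). Over days 28 to 42, 20 of 38 rose and 0 fell in caruncular endometrium (22 and 0 adjusted over the list alone; adjusted p = 1.2e-08, or adjusted p = 0.47 with an estimated correlation). The kinesin KIF23 rose by 1.32 ± 0.25. In intercaruncular endometrium 15 of 37 rose and 3 fell (17 and 4 adjusted over the list alone; adjusted p = 0.016, or adjusted p = 0.7 with an estimated correlation).

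Extracellular matrix genes rose over days 28 to 42, 24 of 34 in intercaruncular endometrium with 1 fall (24 and 1 adjusted over the list alone; median 0.38; adjusted p = 7e-09, or adjusted p = 0.25 with an estimated correlation). Fibronectin (FN1) rose by 0.94 ± 0.09 (adjusted p = 7.9e-08), versican (VCAN) by 1.51 ± 0.18 and the urokinase receptor PLAUR by 1.99 ± 0.26. In caruncular endometrium 11 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.28; adjusted p = 6.4e-07, or adjusted p = 0.42 with an estimated correlation). There FN1 rose by 0.69 ± 0.09 and tenascin C (TNC) by 1.08 ± 0.22. Of 20 genes of the unfolded protein response, 16 rose and 1 fell in intercaruncular endometrium, also when adjusted over the list alone (adjusted p = 2e-06, or adjusted p = 0.52 with an estimated correlation). In caruncular endometrium 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 4.3e-06, or adjusted p = 0.37 with an estimated correlation). ATF3, a stress-induced transcription factor, rose by 1.49 ± 0.16 and 1.20 ± 0.17 in the 2 regions, and DDIT3 fell by 0.56 ± 0.10 in intercaruncular endometrium. Stromal markers rose too, 10 of 18 with 2 falls in intercaruncular (adjusted p = 0.003, or adjusted p = 0.52 with an estimated correlation) and 5 of 18 with 1 fall in caruncular endometrium (adjusted p = 0.0073, or adjusted p = 0.47 with an estimated correlation). MFAP5, a microfibril protein, rose by 1.39 and 1.21.

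**Figure D3:**
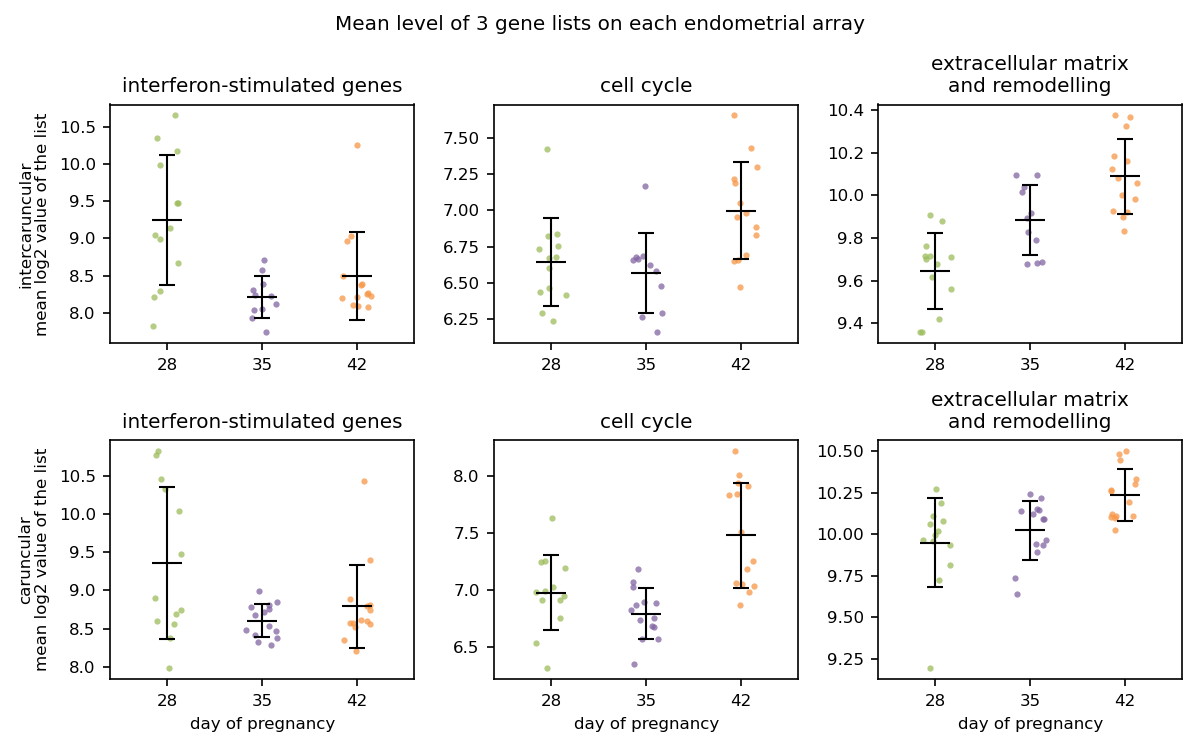
Mean log2 signal of 3 gene lists per array (y axis) by day of pregnancy (x axis) in both endometrial regions (dots are arrays, bars mean ± SD; n = 13, 11 and 14 intercaruncular and 13, 14 and 14 caruncular). Interferon-stimulated genes lie highest on day 28 (9.25 intercaruncular, 9.37 caruncular), cell cycle genes in caruncular endometrium on day 42 (7.48), and extracellular matrix genes on day 42 (10.09 and 10.24).

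Leukocyte markers rose in intercaruncular endometrium by day 42, 12 of 32 with 1 fall (13 and 1 adjusted over the list alone; adjusted p = 0.00056, or adjusted p = 0.59 with an estimated correlation). The monocyte and macrophage markers CD14 and CD68 rose by 1.54 ± 0.23 and 1.66 ± 0.25 and the Fc receptor FCGR1A by 1.74 ± 0.27. In caruncular endometrium 7 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.017, or adjusted p = 0.71 with an estimated correlation). CD14 rose by 0.84. Of 32 uterine gland genes, 14 rose and 4 fell in intercaruncular (16 and 5 adjusted over the list alone; adjusted p = 0.04, or adjusted p = 0.59 with an estimated correlation). In caruncular endometrium 10 rose and 3 fell (12 and 5 adjusted over the list alone; adjusted p = 0.049, or adjusted p = 0.47 with an estimated correlation). In the regions in that order, lactoferrin (LTF) rose by 1.75 ± 0.29 and 1.48 and cystatin C (CST3) by 0.78 ± 0.08 and 0.66. In the prostaglandin list of intercaruncular endometrium 3 of 14 rose and 3 fell (3 and 4 adjusted over the list alone; adjusted p = 0.7, median −0.06 against a mean of 0.12). The synthase PTGES rose by 0.94 ± 0.13 and the degrading enzyme HPGD fell by 0.51. Of 34 nutrient transporters there, 8 rose and 4 fell (adjusted p = 0.41), the cationic amino acid transporter SLC7A1 by 1.95 ± 0.26. Of 9 steroid receptor genes 2 rose and 2 fell (adjusted p = 0.86), of 18 MHC genes 4 rose (adjusted p = 0.15). BOLA-DQB1 fell by 3.57 ± 1.24 while 0 of its 4 other probe sets passed.

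Transcripts of the trophoblast were measured in the endometrial samples. In caruncular endometrium PAG17 and PAG19, pregnancy-associated glycoproteins secreted by trophoblast, rose by 4.37 ± 0.82 and 3.29 ± 0.73 from day 28 to day 42, above the day 28 median in 13 and 9 of 14 arrays. PAG19 was at the lowest value in 13 of 13 day 28 and 5 of 14 day 42 arrays, so that the size of its rise is not measured against a signal above background. TKDP4, another trophoblast gene, fell by 3.02 ± 0.80 and was at the lowest value in 11 of 14 day 42 arrays. Of 31 trophoblast secretory genes, 4 rose and 2 fell (9 and 3 adjusted over the list alone; adjusted p = 0.13), and of 14 trophoblast transcription factors 3 rose (5 adjusted over the list alone; adjusted p = 0.013, or adjusted p = 0.37 with an estimated correlation). In intercaruncular endometrium 0 of 28 secretory genes rose and 3 fell (2 adjusted over the list alone; adjusted p = 0.75), TKDP4 by 2.03 ± 0.50 to the lowest value in 13 of 14 day 42 arrays.

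In all, limma called 7020 of 18771 probe sets between days 42 and 28 in intercaruncular endometrium (2874 higher, 4146 lower) and 2195 of 19002 in caruncular endometrium (1033 higher, 1162 lower). Of 18269 probe sets tested in both, 1923 were called in both, 839 higher in both, 1082 lower in both and 2 in opposite directions. Independence would give 162 higher and 264 lower in both. The regions come from the same cows, so differences between the cows of day 28 and day 42 can be shared by both. These numbers are therefore not the counts to be seen without an effect of day. The difference of the day effect between regions itself passed for 27 probe sets (26 more positive in caruncular endometrium), and for 5 when dim probe sets were left out. Among the 27 were CORO2A, an actin-binding protein (2.15 ± 0.41, adjusted p = 0.012), and the cohesion factor gene CHTF18 (0.71 ± 0.13, adjusted p = 0.0072). CORO2A had 2 other probe sets and CHTF18 had 1, of which 0 were called. Of the 7020 and 2195 probe sets called within the regions, 1579 and 659 reached a fold of at least 1.5. Season group 2 alone gave 3447 and 640.

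Day 35 against day 28 gave 2113 called probe sets in intercaruncular endometrium (709 higher, 1404 lower) and 902 in caruncular endometrium (253 higher, 649 lower). Day 42 against day 35 gave 375 (292 higher, 83 lower) and 493 (445 higher, 48 lower). In caruncular endometrium these counts rested on the 3 arrays labelled caruncular that carried the intercaruncular lowest value: without them 98 and 0 probe sets passed. Without non-lactating day 28 replicate 5 they were 583 and 789. In intercaruncular endometrium, where non-lactating day 35 had 4 arrays, leaving out replicate 1, 2, 3 or 4 gave 1164, 1405, 1677 or 1376 for day 35 against day 28, and 111, 288, 160 or 81 for day 42 against day 35.

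The placenta was compared over the same days, in which the yolk sac regresses and the chorioallantois takes over. In placenta from day 28 to day 42, POSTN, the matrix protein periostin, rose by 5.51 ± 0.76 log2 units (SE; n = 14 on day 42 and 12 on day 28; adjusted p = 3.7e-06). The proteoglycan OGN rose by 5.40 ± 0.63, thrombospondin THBS4 by 3.39 ± 0.31 and NOS2 by 3.13 ± 0.38. TKDP2, a trophoblast Kunitz domain protein, fell by 5.71 ± 1.09 (adjusted p = 0.00029), the cartilage collagen COL2A1 by 4.42 ± 0.63, the carbonic anhydrase CA14 by 3.72 ± 0.28 (adjusted p = 4e-11) and APOB by 3.22 ± 0.99. POSTN, OGN, THBS4 and CA14 were beyond the day 28 median in 14 of 14 day 42 arrays. PAG6 rose by 2.13 ± 0.39, PAG3 by 2.18 ± 0.53 and the lactogen CSH2 by 1.21 ± 0.31 (adjusted p = 0.0041). Without the 3 day 28 arrays that stood apart these were 1.19, 0.86 and 0.45.

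Stress response genes rose in placenta, 18 of 25 with 1 fall (20 and 1 adjusted over the list alone; median 0.68; adjusted p = 2.1e-09, or adjusted p = 0.17 with an estimated correlation). The mRNA decay factor ZFP36 rose by 1.26 ± 0.13 and JUN by 0.88 ± 0.12. As this list also covers the response to tissue dissociation, stress in the placenta cannot be told apart from handling of the samples. Of 44 oxidative phosphorylation genes 33 fell and 0 rose (34 and 0 adjusted over the list alone; median −0.17; adjusted p = 7.1e-08, or adjusted p = 0.64 with an estimated correlation), NDUFA5 by 0.25 ± 0.05 (−0.15 without the 3 arrays). Of 39 cell cycle genes 20 fell and 0 rose (21 and 2 adjusted over the list alone; adjusted p = 0.00021, or 0.64 with an estimated correlation), RRM2 by 0.37 ± 0.06. Of 17 yolk sac markers 7 fell (8 adjusted over the list alone; adjusted p = 0.0029, or 0.64 with an estimated correlation). Of 14 hepatocyte markers 6 fell (7 adjusted over the list alone; adjusted p = 0.0094, or 0.64 with an estimated correlation) and of 16 lipoprotein genes 9 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.011, or 0.64 with an estimated correlation). The fibrinogen chain FGG fell by 2.54 ± 0.78, transthyretin (TTR) by 2.22 ± 0.75 and the lipid transfer gene MTTP by 2.93 ± 0.56. Of 14 placental steroid synthesis genes 5 rose (7 adjusted over the list alone; adjusted p = 0.0052, or 0.64 with an estimated correlation). The estrogen sulfotransferase SULT1E1 rose by 1.95 ± 0.25, HSD3B1 by 1.47 ± 0.34 and CYP17A1 by 1.24 ± 0.32. CYP11A1 differed by 0.63 ± 0.31 (adjusted p = 0.12), and by 0.06 without the 3 arrays. CYP19A1, the aromatase, was at the lowest value in 7 of 14 day 42 and 11 of 12 day 28 arrays, which leaves the size of its change unmeasured. Of 21 genes of the unfolded protein response 4 rose (adjusted p = 0.0074, or 0.64 with an estimated correlation, and 0.81 without the 3 arrays). Endothelial markers rose, 4 of 13 (adjusted p = 0.0052, or 0.64 with an estimated correlation), the transcription factor ERG by 1.24. Without the 3 arrays 10 cell cycle, 11 yolk sac and 11 hepatocyte genes fell and 10 endothelial genes rose.

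Of 32 trophoblast secretory genes, 6 rose and 2 fell (9 and 2 adjusted over the list alone; median 0.58; adjusted p = 0.002, or adjusted p = 0.64 with an estimated correlation). Without the 3 day 28 arrays that stood apart 3 rose and 9 fell (median −0.07; adjusted p = 0.28). The list means of those arrays were 10.78, 9.82 and 9.14, against 12.73 to 13.13 in the other 9 day 28 arrays. Without them HSD3B1 rose by 0.65 and CYP17A1 by 0.56. Epithelial markers rose in 9 of 16 genes and fell in 2 (adjusted p = 0.041, or adjusted p = 0.64 with an estimated correlation; adjusted p = 0.28 without the 3 arrays). Of 14 erythroid genes 4 rose and 1 fell (adjusted p = 0.052, and 0.0073 without the 3 arrays, or adjusted p = 0.49 there with an estimated correlation). The hemoglobin chain HBB rose by 3.10 ± 0.41 (adjusted p = 1.7e-06). Of 13 smooth muscle genes 5 rose (adjusted p = 0.068, and 0.0003 without the 3 arrays, or adjusted p = 0.36 there with an estimated correlation), the smooth muscle myosin MYH11 by 1.94. Of 21 imprinted genes 7 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.13, and 0.0011 without the 3 arrays, or adjusted p = 0.36 there with an estimated correlation). DLK1 rose by 1.89 ± 0.24 and NNAT fell by 1.53 ± 0.21. Among 38 interferon-stimulated genes 12 fell and 3 rose (14 and 4 adjusted over the list alone; adjusted p = 0.079), and ISG15 fell by 2.45 ± 0.85 (below the day 28 median in 11 of 14 arrays). Its call ended without the 3 arrays, at −2.29, where 6 of the list fell and 2 rose. Of 23 leukocyte markers 6 rose (adjusted p = 0.079, median −0.01 against a mean of 0.29), CD14 by 1.21 ± 0.16.

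In all, limma called 5003 of 18740 probe sets between days 42 and 28 in placenta (2243 higher, 2760 lower), 1951 between days 35 and 28 (912 higher, 1039 lower) and 69 between days 42 and 35 (40 higher, 29 lower), where POSTN rose by 3.15 ± 0.73. Without the 3 day 28 arrays that stood apart, 872 and 587 passed in the comparisons of day 35 with day 28 and of day 42 with day 35. Without lactating day 42 replicate 7 or non-lactating day 42 replicate 4 the latter count was 23 or 41. A fold of at least 1.5 was reached by 1603 of the 5003, and season group 2 alone gave 1621.

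**Figure D4:**
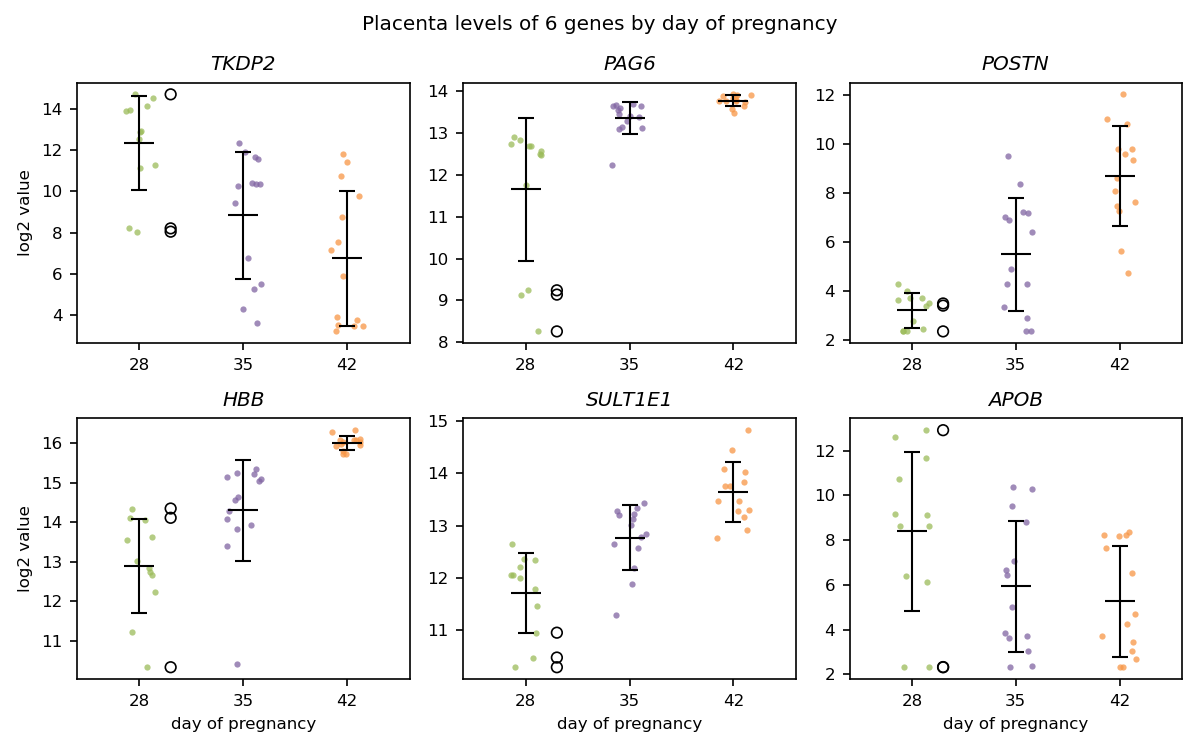
Log2 signal in placenta of 6 genes (y axis) by day of pregnancy (x axis; n = 12, 14 and 14; dots are arrays, open circles the 3 day 28 arrays that stood apart, bars mean ± SD). TKDP2 and APOB lie lower on day 42 than on day 28 (−5.71 and −3.22), and PAG6, POSTN, HBB and SULT1E1 lie higher (2.13, 5.51, 3.10 and 1.95).

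The liver was compared over the same days and limma called 0 probe sets in each pair of days, with 534 (day 42 against day 28), 1100 (day 35 against day 28) and 568 (day 42 against day 35) at an unadjusted p under 0.05, where 901 would be expected by chance. Between days 42 and 28, PRIMPOL differed by 0.77 ± 0.20 (adjusted p = 1), GHR by 0.02 ± 0.17 and IGF1 by −0.06 ± 0.24. The cholesterol synthesis list was higher on day 42 than on day 28 (median 0.12; adjusted p = 1.2e-05, or adjusted p = 0.88 with an estimated correlation) with 0 of 17 genes called. Cell cycle genes were higher on day 42 than on day 35 (adjusted p = 1.7e-13, or adjusted p = 0.58 with an estimated correlation), also with 0 called. Without lactating day 35 replicate 7, 2 probe sets passed between days 35 and 28.

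Both endometrial regions were then compared with each other, as they differ in glands and in contact with the placenta. In caruncular relative to intercaruncular endometrium, the prolactin-related proteins PRP6 and PRP1, products of trophoblast, were higher by 4.43 ± 0.43 and 4.39 ± 0.47 log2 units (SE; n = 41 and 38; PRP6 above the intercaruncular median in 39 of 41 arrays; adjusted p = 1.7e-14), PAG17 by 3.01 ± 0.39 and CSH2 by 2.98 ± 0.39 (at the lowest value in 26 of 38 intercaruncular arrays, so that the size is not measured against a signal above background). COL26A1, a collagen, was higher by 3.45 ± 0.17 (adjusted p = 4.5e-28). NPPC, the C-type natriuretic peptide, was higher by 3.32 ± 0.32 (at the lowest value in 31 of 38 intercaruncular arrays, with the same limit on its size) and APC by 3.70 ± 0.22. The translation factor EIF4E3 was lower by −3.91 ± 0.20 (40 of 41 arrays; adjusted p = 1e-27), the metalloprotease ADAM12 by −3.75 ± 0.22 (41 of 41 arrays) and E-cadherin (CDH1) by −3.26 ± 0.19.

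Smooth muscle genes were lower in caruncular endometrium, 11 of 13 with 0 higher (12 and 0 adjusted over the list alone; median −1.04; adjusted p = 2.5e-05, or adjusted p = 0.94 with an estimated correlation). The difference was −1.85 ± 0.12 for caldesmon (CALD1) and −1.79 ± 0.33 for desmin (DES). Leukocyte markers were called higher in 25 of 32 genes and lower in 1 (median 0.73), the T cell genes CD3E by 1.00 and CD8B by 1.27, and plasma cell genes in 6 of 7 (1 lower; median 1.02). Neither list passed against the other genes (adjusted p = 0.61 and 0.79). Of 38 cell cycle genes 30 were higher and 1 lower (adjusted p = 0.11), of 14 endothelial markers 12 and 1 (adjusted p = 0.66). Of 23 angiogenesis genes 15 were higher and 3 lower, and of 31 trophoblast secretory genes 13 and 0 (12 and 0 adjusted over the list alone; adjusted p = 0.81). Interferon-stimulated genes were higher in 15 of 39 and lower in 3 with a median of 0.28, while the list test pointed down. Oxidative phosphorylation genes were higher in 32 of 44 and lower in 4 (adjusted p = 0.041, or 0.057 without the 3 arrays labelled caruncular that carried the intercaruncular lowest value). In the epithelial list 5 of 16 genes were lower with 0 higher, CLDN7 by −0.97 (adjusted p = 0.041, or 0.057 without them). Of 17 cholesterol synthesis genes 5 were higher and 7 lower, MVK, the mevalonate kinase, by −1.57 (adjusted p = 0.041). These calls were lost with an estimated correlation.

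In all, limma called 12919 of 19504 probe sets between the regions, 8479 higher and 4440 lower in caruncular endometrium, 3040 of them with a fold of at least 1.5 and 8493 when dim probe sets were left out. The arrays of each region had been normalized separately, so that region and array processing cannot be told apart in any of these values, and the median over all probe sets was shifted by 0.07. Of the 9 other probe sets for the 10 genes with the largest falls, 1 was called in the same direction, against 4 of 7 for the 10 genes with the largest rises. On an axis of 1418 probe sets that separates the regions, the 3 arrays labelled caruncular with the intercaruncular lowest value lay at or below 0.01, within the intercaruncular arrays. The same axis separates the separately processed sets, so this position alone does not show the region of these arrays. Over the 39 genes on it whose separate probe sets agreed they lay at or below 0.04, against 0.49 or more in the other caruncular arrays. Intercaruncular arrays reached 0.487 over these genes, so close to the other caruncular arrays that this position does not show the region either.

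**Figure D5:**
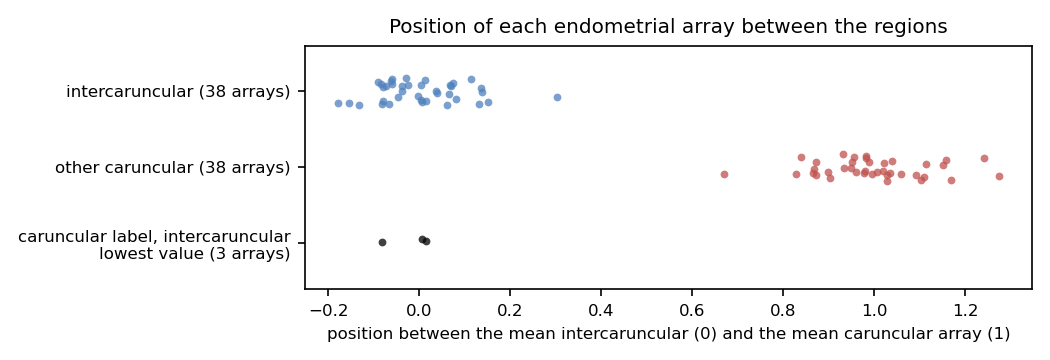
Position of each endometrial array (y axis: groups of 38 intercaruncular arrays, 38 caruncular arrays and the 3 arrays labelled caruncular that carry the intercaruncular lowest value). The x axis gives the position over 1418 probe sets, each weighted by its difference between the regions (unitless, 0 at the intercaruncular and 1 at the caruncular mean). The highest intercaruncular array is at 0.30, the lowest of the other caruncular arrays at 0.67, and the 3 arrays lie at or below 0.01.

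Season entered as a covariate and was also tested, group 2 minus group 1. Season group may coincide with a batch of collection or array processing, which the labels do not give. Season and batch therefore cannot be told apart in these values. In placenta 304 probe sets passed (33 higher, 271 lower), among them TMED9 (−0.72 ± 0.10). The apoptosis gene BAX differed by −2.06 ± 0.28, below the group 1 median in 25 of 25 group 2 arrays. The kinase ABL1 differed by −1.37 ± 0.19, while 0 of its 2 other probe sets passed. In caruncular endometrium 8 passed (7 higher, 1 lower), with POMK, a kinase of dystroglycan glycosylation, higher by 0.58 ± 0.09 in 26 of 26 group 2 arrays (limma, adjusted p = 0.0088). In that tissue 1 passed without the 3 arrays that carried the intercaruncular lowest value and 27 without non-lactating day 28 replicate 5. In liver 2 probe sets without a gene symbol passed, both lower. IDH2, an isocitrate dehydrogenase, differed by −0.32 ± 0.06 (adjusted p = 0.051). In intercaruncular endometrium limma called 0, with 1508 at an unadjusted p under 0.05, and TIMM9 (0.16) and CHD2 (−0.20) had the smallest p.

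Whether the lactation effect changed with the day of pregnancy was the last comparison. limma called 0 probe sets for the interaction in each tissue, with 783 in liver, 808 in intercaruncular endometrium, 649 in caruncular endometrium and 736 in placenta at an unadjusted p under 0.05. The smallest p were those of NAA15 and GCSH in liver (adjusted p = 0.64), UBL7, TIMM9 and ARSB in intercaruncular endometrium (0.96), AP1M2, RNF187 and BRPF1 in caruncular endometrium (0.93), and DNAJA4, ATG14 and METTL1 in placenta (0.98).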

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

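Of the tests in this part, those of intercaruncular RNA under caruncular labels and of joint normalization, of the cow behind a liver array, of the yolk sac and endometrium in placenta samples, and of the maturity of lactating placenta replicates 5 and 6 were chosen only after the result was seen. Single arrays far from the rest of their group were sought in 72 combinations of group and measure, and 16 were found where about 1 in 20, or 3.6, would come up by chance. The median correlation with the tissue's other arrays was 0.9853 in caruncular lactating day 35 replicate 8, 0.9851 in caruncular lactating day 42 replicate 4 and 0.955 in caruncular non-lactating day 28 replicate 5. It was 0.9902 in liver lactating day 42 replicate 4, 0.9902 in placenta lactating day 35 replicate 6 and 0.9499 in placenta non-lactating day 28 replicate 2. The other arrays of these groups had 0.9888 or more. The percentage of probe sets at the lowest value stood apart in caruncular lactating day 35 replicate 8 (24%), intercaruncular lactating day 35 replicate 4 (23.2%), intercaruncular non-lactating day 35 replicate 2 (23.9%), liver non-lactating day 28 replicate 3 (27.4%) and placenta non-lactating day 28 replicate 2 (23.8%). The median log2 signal stood apart in caruncular lactating day 42 replicate 6 (6.65), caruncular non-lactating day 28 replicate 5 (6.23), intercaruncular lactating day 42 replicate 8 (6.45), intercaruncular non-lactating day 35 replicate 3 (6.53) and placenta non-lactating day 28 replicate 3 (6.54). In intercaruncular non-lactating day 35 the other arrays were all at 6.54, or all at 24.1% for the share at the lowest value. Replicate 3 there stood apart by no more than the rounding of the values, yet counts among the 16. The lactation effect differed between liver and intercaruncular endometrium, caruncular endometrium and placenta for 542, 430 and 601 probe sets, and the effect of day 42 against day 28 differed between the endometrial regions for 27.

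The first pattern is that 3 arrays labelled caruncular from day 35 carry the exact lowest value of the intercaruncular arrays. In 17 probe sets with separate clusters of signal between cows, the liver arrays closest to the 3 had title numbers that are missing among the intercaruncular arrays. Their correlations were 0.972, 0.893 and 0.955, which concerns the cow and not the region. Over 22 such probe sets, the liver arrays closest to the 2 non-lactating arrays were closest to no other caruncular array. The liver array closest to lactating replicate 8 was also closest to caruncular lactating day 35 replicate 7. Those 2 non-lactating cows may thus lack another caruncular array as well, so the missing title numbers do not show the region. On an axis of 1418 probe sets that separates the regions (0 for the mean intercaruncular, 1 for the mean caruncular array), the highest of the 3 lay at 0.014, and their median rank correlations were 0.99 to 0.992 with intercaruncular and 0.981 to 0.983 with caruncular arrays, but both measures also separate the array sets that were processed separately. The 3 lay below every other caruncular array over the 39 genes on the axis whose separate probe sets all went the same way (8 went both ways). The highest of the 3 was at 0.037 there and the lowest other caruncular array at 0.494. Over the means of 36 gene lists these positions were 0.072 and 0.078, too close to separate. Over the 39 genes and over the list means, the 3 lay below the highest intercaruncular array (0.487 and 0.737), where intercaruncular RNA would lie. The limits written before these tests on how far the regions must lie apart were not met. Intercaruncular arrays reached 0.487 and 0.737, and the other caruncular arrays fell to 0.078 over the list means. Caruncular RNA normalized together with the intercaruncular arrays therefore cannot be told apart from intercaruncular RNA. The other 11 caruncular arrays of that day had a median of 0.978 on the first axis and 0.913 over the 39 genes. Over the list means, where the regions overlapped, their median was 0.712. The median on the first axis was above the limit written for a biological shift of caruncular tissue on day 35. These arrays helped to define the axes, and the first axis also separates the processed sets, so their positions do not decide on such a shift. They show only that the 3 lay apart from most other arrays of their own day.

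The second pattern is that 2 pairs of arrays with different group labels correlate more closely than any other pair of their tissue: liver lactating day 35 replicate 7 with lactating day 28 replicate 5 (0.999; next pair 0.9968) and placenta lactating day 42 replicate 7 with non-lactating day 42 replicate 4 (0.9986; next pair 0.9975). Over 62 probe sets with separate clusters of signal between cows, the liver pair differed least of all 820 pairs (rank 1; root mean square difference 0.54, smallest other 1.81), which is consistent with 1 RNA hybridized under both labels. The liver array of day 35 also correlated at −0.115 with the intercaruncular array of its title number. The other pairs had a median of 0.931 and a lowest value of 0.364. This liver array may therefore come from another cow than its title says. Its closest intercaruncular array, at 0.743, was lactating day 28 replicate 5, which was also the closest to the other liver array of the pair (0.716). Both liver arrays may thus come from 1 cow, which would count 2 times among the lactating liver arrays. For the placenta pair the same measure gave rank 3 of 780 (1.28, smallest other 1.22), so 2 other pairs, whose relation was not tested, were closer, and whether the pair is 1 RNA or 2 cows cannot be told apart by this measure. No biological explanation was tested for this pattern, since the design names none.

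The third pattern is that 3 placenta arrays of day 28 stand apart, and they do so in different ways. In non-lactating replicate 2, the position on an axis of 872 probe sets that change from day 28 to day 35 was below every other day 28 array (1 of 1 arrays; −1.195, lowest other −0.594), though on 587 probe sets that change from day 35 to day 42 it lay at −0.56, within the others (−0.80 to −0.26), and the mean of the yolk sac markers was above them (1 of 1 arrays; 11.78, highest other 11.09), so a less advanced conceptus or more yolk sac or fetal tissue may account for it; IFNT2, the interferon of the elongating trophoblast, was at 13.02 there (highest other day 28 array 5.74). In lactating replicates 5 and 6, 0 of 2 arrays were less advanced on the first axis (0.28 and 0.359). These 2 arrays also differed from the others in stromal and trophoblast levels, so this axis cannot decide on the maturity of the conceptus. More yolk sac, or more fetal tissue with the same serum protein transcripts, is argued against, with 0 of 2 arrays with more yolk sac signal (7.52 and 7.74, lowest other 8.63). Fetal tissue without these transcripts was not tested. The median of 6 endometrial transcripts was 4.24, 2.01 and 3.95 in the 3 arrays, 2.69 over the other day 28 arrays and 12.39 in endometrium: 0 of 3 came within 2 log2 units of endometrium, which argues against a large share of it, while a trace in the arrays at 4.24 and 3.95 stays open. Sampling of another part of the membranes stays open for lactating replicates 5 and 6 and was not tested. Their trophoblast secretory means were 9.82 and 9.14, against 12.73 to 13.13 in the other day 28 arrays. Their stromal means were 10.79 and 11.06, against 9.43 to 10.18.

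Regroupings of the arrays, 100 for each count with the real one included, were used to ask whether chance can be excluded. It can be excluded, with 1 regrouping, the real one, reaching the count, for lactation in liver (1776, highest other 19), for day 42 against day 28 in intercaruncular (7020, 75) and caruncular endometrium (2195, 20) and placenta (5003, 22), and for day 35 against day 28 in the same tissues (2113, 173; 902, 49; 1951, 3). The same holds for day 42 against day 35 in intercaruncular (375, 185) and caruncular endometrium (493, 48). In caruncular endometrium the regroupings included the 3 day 35 arrays labelled caruncular that carry the intercaruncular lowest value. Without these arrays 0 probe sets were called for day 42 against day 35, and far fewer for day 35 against day 28. For these 2 counts the regroupings therefore do not tell an effect of day from the region or processing of the 3 arrays. Chance can also be excluded for the liver differences in lactation effect (542 against 91, 430 against 4 and 601 against 3) and for the endometrial regions (12919, 1). For season in liver (2, 1) and caruncular endometrium (8, 1), only the real grouping reached the count as well. With so few probe sets this does not exclude chance, and the caruncular count was 1 without the same 3 arrays. For day 42 against day 35 in placenta (69) and season in placenta (304), 2 of 100 regroupings were as large, the real one included. Their highest others, 2081 and 4488, were several times the real counts, so chance is excluded less firmly there. The cause of these high counts was not tested. For the difference in the day effect between endometrial regions (27), 5 of 100 were as large, the highest at 578, and chance cannot be excluded. Where the count was 0, all 100 regroupings were as large by construction. The highest others were 1, 1, 4 and 607 in liver (the 3 pairs of days and the interaction), 1185, 19 and 2 in intercaruncular endometrium (lactation, interaction, season), 4 and 80 in caruncular endometrium (lactation, interaction) and 6 and 1706 in placenta (lactation, interaction).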

How the results depend on the processing

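Of the alternatives in this part, those that leave out arrays that stood apart or that belonged to an unusually similar pair, and the block for the cow over both tissues, were chosen after seeing the data. Dropping the season term, trended and robust variances and dropping the interaction moved no count of called probe sets by more than 1.5 times. Of 8647 values of named genes under alternatives, 7896 kept direction and side of the threshold, 657 kept direction and lost the call, 40 gained it and 54 turned. Between 23.2% and 28.4% of the probe sets of an array were at the lowest value, where signal over background limits what can be seen. Fewer arrays were fitted for single season groups and fewer probe sets tested without dim ones; for the other settings the cause was not tested.

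Asking for a fold of at least 1.5 left 271 for lactation in liver and, for day 42 against day 28, 1579 in intercaruncular endometrium, 659 in caruncular endometrium and 1603 in placenta. Season group 1 alone gave 82, 31, 63 and 12 for lactation in liver, intercaruncular endometrium, caruncular endometrium and placenta, and 21, 2952, 677 and 867 for day 42 against day 28. Season group 2 alone gave 910 and 2 for lactation in liver and placenta, and 3447, 640 and 1621 for day 42 against day 28 in intercaruncular endometrium, caruncular endometrium and placenta. A block for the title number gave 618 and 1 for lactation in liver and placenta, and array weights gave 1 in placenta. The title numbers do not pair lactating with non-lactating cows: median correlations of pairs were −0.046 in liver, 0.055 in intercaruncular endometrium, 0.007 in caruncular endometrium and 0.105 in placenta. Quantile normalization left 574 for day 35 against day 28 in caruncular endometrium. Without dim probe sets there were 299 and 44 for day 42 against day 35 in caruncular endometrium and placenta, 5 for the day effect difference between regions and 8493 between the regions.

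Without the 3 arrays labelled caruncular that carry the intercaruncular lowest value, 98 were called for day 35 against day 28, 0 for day 42 against day 35 (by limma) and 1 for season in caruncular endometrium, and 2 instead of 4 lists passed between the regions. Without the 3 placenta day 28 arrays that stood apart, 872 were called for day 35 against day 28 and 587 for day 42 against day 35. Single arrays were left out only where they were members of the 2 most similar pairs (2 in liver, 2 in placenta), stood apart in caruncular endometrium (2) or belonged to the smallest intercaruncular group (4). Liver lactating day 42 replicate 4, placenta lactating day 35 replicate 6 and placenta non-lactating day 28 replicate 2, which stood apart, were not left out alone. This gave 0 to 2 for day 35 against day 28 in liver, 1164 to 1677 in intercaruncular and 583 to 859 in caruncular endometrium. It gave 81 to 288, 343 to 789 and 23 to 41 for day 42 against day 35 in intercaruncular endometrium, caruncular endometrium and placenta, and 9 to 27 for season in caruncular endometrium. It also turned uncalled values for lactation, ISG15 in intercaruncular (−0.05 to 0.07) and IGF1 in caruncular endometrium (−0.02 to 0.02), and IGF1 for day 42 against day 28 in caruncular endometrium (−0.01 to 0.05). With an estimated correlation, 0 lists passed in every comparison within a tissue, for the day effect difference and between the regions, and 2 passed for each of the liver differences (from 5, 9 and 11 lists).

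Of the genes that turned, NDUFA6 was the only called one, for day 42 against day 28 in caruncular endometrium (0.02 in season group 1). Turned without a call, in the additive model, were GHR (0 in liver, day 42 against day 28) and OXTR (0.01 in intercaruncular endometrium, lactation). With array weights these were IGF1 (−0.14 in intercaruncular endometrium) and GHR (−0.11 in caruncular endometrium) for day 42 against day 28. For lactation they were IGF1 (−0.08) and ISG15 (0.11) in caruncular endometrium and CSH2 (0.04), CYP11A1 (−0.05) and SSLP1 (0.02) in placenta. In season group 1, lactation values turned for OXTR in intercaruncular endometrium (0.03), for CFB (−0.03), CRELD2 (−0.02), HERPUD1 (−0.07), HSP90B1 (−0.02) and MANF (−0.05) in caruncular endometrium. In placenta they turned for CSH2 (0.41), CXCL5 (0.27), CYP19A1 (0.11), DLX5 (0.28), ETS2 (0.18), FDPS (0.06), FDX1 (0.22), HSD17B2 (−0.02), HSPB6 (−0.03), ISG15 (0.22), PAG15 (0.17), PAG21 (0.30), SSLP1 (0.06), SULT1E1 (0.17) and TAT (0.13). Day 42 against day 28 turned there for IGF1 in intercaruncular endometrium (−0.20), GHR (−0.16) and IGF1 (−1.19) in caruncular endometrium and CYP19A1 in placenta (0.08). In season group 2, GHR turned for day 42 against day 28 in liver (−0.11), and lactation values turned for IGF1 in liver (−0.15), ISG15 in intercaruncular endometrium (0.28), FEN1 (0), IGF1 (−0.27) and IGFBP5 (−0.21) in caruncular endometrium and CYP11A1 (−0.26) and S100A8 (0.05) in placenta. With the title block IGF1 turned for lactation in caruncular endometrium (−0.04). Without the 3 placenta day 28 arrays, lactation values turned for CSH2 (0.05), CYP11A1 (−0.01), HSD17B2 (−0.01), HSPB6 (−0.05), SMTN (−0.03) and SSLP1 (0.03).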

Other observations

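Of the tests in this part, those without arrays that stood apart were chosen after seeing the data, and no further explanations were tested. In intercaruncular endometrium from day 28 to day 42, the binding proteins of insulin-like growth factors IGFBP2 and IGFBP4 rose by 2.19 ± 0.30 and 1.02 log2 units and the cytokine signalling inhibitor SOCS3 by 1.99 (n = 14 on day 42 and 13 on day 28). Of 13 measured genes of the GH-IGF axis there 4 rose and 0 fell, and the list did not pass (limma, adjusted p = 0.057), while IGF1 itself differed by 0.03 ± 0.38 and GHR by 0.14 ± 0.40. Of 16 acute phase genes in intercaruncular endometrium 7 rose and 2 fell, and the list did not pass (adjusted p = 0.057). CFB, a complement factor, rose by 1.46 there and by 1.18 in caruncular endometrium, and LBP, which binds lipopolysaccharide, by 2.18 in caruncular endometrium. There 6 of 21 rose and 0 fell (adjusted p = 0.047, or adjusted p = 0.7 with an estimated correlation, and 0.054 without the 3 arrays labelled caruncular that carry the intercaruncular lowest value). In intercaruncular endometrium the urea cycle genes ASS1 and ASL rose by 1.20 and 1.46, and the cortisol-activating enzyme HSD11B1 by 1.79. The bile acid transporter SLC10A1 rose by 3.09 ± 0.47 in placenta from day 28 to day 42, the lipoprotein lipase LPL by 1.26 and PDK4 by 1.56. ME1, the malic enzyme, fell by 1.65 and the fatty acid binding protein FABP3 by 1.63, or by 1.01 without the 3 day 28 arrays that stood apart.

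Between days 35 and 42 other lists moved at the preset correlation. In intercaruncular endometrium 2 of 17 cholesterol synthesis genes fell (8 adjusted over the list alone; adjusted p = 2.2e-05, or adjusted p = 0.82 with an estimated correlation) and 5 of 32 leukocyte markers rose (9 adjusted over the list alone; adjusted p = 0.00012, or adjusted p = 0.88 with an estimated correlation). In caruncular endometrium 8 of 31 trophoblast secretory genes rose (12 adjusted over the list alone; adjusted p = 0.0001, or adjusted p = 0.87 with an estimated correlation), PAG17 by 3.87 ± 0.81 and PRP1 by 3.74, in a comparison in which 0 probe sets passed without the 3 arrays labelled caruncular that carry the intercaruncular lowest value. Hepatocyte markers in caruncular endometrium were higher in season group 2 (adjusted p = 0.0002, or adjusted p = 0.76 with an estimated correlation). Their mean had a median of 4.33 and a highest value of 4.47 over the 15 arrays of season group 1, and a median of 4.63 and a highest value of 9.33 over the 26 arrays of season group 2, of which 16 lay above every array of group 1.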
